A study of Apostichopus japonicus with 3 samples.

How the data were processed

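Total RNA of respiratory trees at non-aestivation, deep aestivation and arousal was enriched for poly(A) RNA on oligo(dT) beads, fragmented, and primed with random hexamers, per the labels' protocols. The kit is not described as keeping strand, so reads of overlapping opposite transcripts cannot be told apart. The submitters' processing notes name CASAVA 1.5. The read aligner is not given in the sources used here. Per the file headers and the accompanying column description, the authors deposited for each library the count of reads mapped uniquely to each isotig of a reference transcriptome assembly, with the isotig's length, gene ontology terms and best protein match. The deposited RPKM values are, per the file headers, those counts divided by isotig length in kilobases and by the uniquely mapped reads in units of 1e6. Recomputed from the counts, all RPKM values matched within a relative tolerance of 1e-09, and the counts of each library summed to the total in its header.

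Each library is 1 group of 1. Totals were 0.941, 0.887 and 0.963 M reads for non-aestivation, deep aestivation and arousal, so that 1 read on an isotig of 1 kb is worth 1.06, 1.13 and 1.04 RPKM. An isotig missing from a table was taken as 0 reads. Of 20991 isotigs with a read in any library, 10896 had at least 20 reads summed over the 3 libraries and entered the comparisons. Of these, 5686 had a protein match and 3369 a match with an informative name. Names are those of the best match, often in another animal, and were taken from the files. The gene table of the reference genome could not be joined to isotig names and was not used, so no genome positions are given.

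An isotig was called higher or lower when its log2(RPKM + 0.5) differed by at least 1, which is 2-fold, a scale that understates the change of rare transcripts. With 1 library per group no p-value was computed. The chance level is the mean over 100 Poisson redraws of the reads from the rate common to both libraries. For named isotigs the ratio of read rates is given with an exact (conditional binomial, Clopper-Pearson) 95% interval. Shares of reads have exact binomial intervals. For a named isotig with 0 reads in 1 library, the fold is stated as at least the nearer bound of the exact ratio interval. Where list members at 0 reads were set to their bound, a count of 0 was taken as a floor of 3 reads. Reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only. Differences between animals or library preparations are not covered. Unique counting splits or drops reads of near-identical isotigs, so for isotigs that share a protein name the sum over the name is given where it differs much.

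Before the data were examined, 31 lists of pathway and cell type marker genes were fixed as patterns on protein names. A list's median log2 ratio was ranked among 10000 random lists of the same size, matched in 20 bins of mean expression and drawn from isotigs with a protein match. Lists with fewer than 5 measured members got no percentile. Some patterns matched more than intended: the complement list holds ATP synthase subunit C3, bindin in the gonad list matched the word binding, p70 in the insulin list matched heat shock protein 70, integrin in the coelomocyte list matched disintegrin, and lipase matched phospholipase. Named transcripts followed a rule also fixed then. It took per comparison the 8 higher and 8 lower isotigs with the largest change among those with at least 100 reads in the higher library and an informative name. It also took from each list the most abundant member and the largest change, and the 10 isotigs with most reads in each library. Further members named as examples of a list (MCM6, citrate synthase, ATP synthase subunits, ficolin and C-type lectin isotigs, ribosomal protein L34 and axonemal dynein) were chosen after their values were seen, as were bindin and the other transcripts described only in the closing section.

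Alternatives were pseudocounts of 0.1 and 1, no filter or at least 100 reads, TMM factors (edgeR 4.0.16), median-of-ratios factors (DESeq2 1.42.0), totals without the most abundant isotigs, an interval criterion, 1 isotig per name and split reads. Added after seeing the data were random lists from all isotigs, centring on matched isotigs, a corrected gonad pattern and sums over isotigs of 1 name. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3. The rule of size was tested on simulated data for deep aestivation against non-aestivation, over 10896 isotigs with 200 changed. It recovered 86.5% of isotigs changed 3-fold and 99% of those changed 8-fold, 0 of them in the wrong direction, and also called 622 and 621 unchanged isotigs. Intervals held the true ratio for 96.7% and 96.3% of isotigs. Of 100 simulated lists of 30 isotigs without an effect, 5 lay outside the middle 95% of random lists. These lists were drawn at random with independent values, so lists of related isotigs were not covered. The deposited coverage column was not used here.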

Results

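The transcriptome of the respiratory tree was compared across aestivation in the sea cucumber Apostichopus japonicus. The respiratory tree is the branched organ of the body cavity through which sea cucumbers take up oxygen, and aestivation is a summer dormancy in which feeding and movement stop and metabolism is lowered. The 3 stages were non-aestivation, deep aestivation and arousal from aestivation, with 1 poly(A) RNA library each. At least 15 individuals were used per stage, but the labels do not say how their RNA was combined. With 1 library per stage there was no replicate, so no difference has a replicate check and each comparison is between libraries. Intervals are exact, at 95%, and cover counting error only. The exception is intervals named as bootstrap, which cover the spread over isotigs. Reads had been counted on isotigs, the assembled transcripts of a reference transcriptome, and several isotigs can come from 1 gene and share its reads. The non-aestivation library held 0.941 M (1e6) uniquely assigned reads, the deep aestivation library 0.887 M and the arousal library 0.963 M. In the same order, 18915, 17992 and 18141 isotigs had a read, and 10896 isotigs with at least 20 reads over the 3 libraries were compared.

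Major yolk protein 1 (isotig13120), an iron-binding transferrin-family protein known from echinoderm gut, coelomic fluid and gonads, was the most abundant named transcript outside arousal. It took 7.13% of the reads in non-aestivation, 6.84% in deep aestivation and 0.207% in arousal. The 10 isotigs with most reads together took 19.97% in non-aestivation (interval 19.9 to 20.1), 23.6% in deep aestivation (23.5 to 23.7) and 20.7% in arousal (20.6 to 20.8). Of these leading isotigs, 3 without a protein match (isotig22175, isotig24195 and isotig10678) took 9.95%, 12.7% and 15.9% of the reads in the 3 stages. Mitochondrial cytochrome c oxidase subunit 1 and ATP synthase F0 subunit 6 were also among the leading transcripts, at 10196 and 7882 RPKM in non-aestivation. The profile of deep aestivation lay closer to arousal than to non-aestivation. Across the 10896 isotigs, which are not independent replicates, Pearson's r of log2(RPKM + 0.5) was 0.87 between deep aestivation and arousal, 0.76 between deep aestivation and non-aestivation and 0.77 between arousal and non-aestivation. Spearman's rho was 0.87, 0.74 and 0.75, and counting error alone would leave r at about 0.95.

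The first comparison asked which transcripts differ in deep aestivation. In deep aestivation, the lists for the cell cycle, the tricarboxylic acid cycle, chaperones, translation factors and RNA splicing had lower medians than matched random lists, though not every member fell, while betaine-homocysteine S-methyltransferase 1-like, glycine N-methyltransferase-like, a Krüppel-like factor and serum amyloid A were higher. Other enzymes of methyl-group metabolism went in both directions. Betaine-homocysteine S-methyltransferase 1-like (isotig13345), which remakes methionine from homocysteine, went from 38.7 to 424.7 RPKM and was 11.0-fold higher (8.75 to 13.9). Glycine N-methyltransferase-like (isotig19436), which spends S-adenosylmethionine, was 7.98-fold higher (5.40 to 12.2). The transcription factor KLF2/4 (isotig09309) rose 8.74-fold (7.47 to 10.3), from 88.7 to 775.7 RPKM.

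Serum amyloid protein A, an acute-phase protein of vertebrates, had 1 read in non-aestivation and 162 in deep aestivation on isotig08093, and its 2 isotigs summed were 106-fold higher. Lactase-phlorizin hydrolase, a glycosidase, had 0 and 119 reads on isotig14693, at least 33.7-fold higher, and was 21.9-fold higher summed over its 3 isotigs. An angiopoietin-like protein rose 12.9-fold (6.997 to 26.5), a protein with EGF-like domains (isotig26818) 16.4-fold (10.5 to 27.3), and the Sec61 gamma subunit of the endoplasmic reticulum translocon 8.19-fold (4.997 to 14.2). Oxysterol-binding protein-like OSBPL10 was 7.85-fold higher, matrix metalloproteinase 16 was 2.80-fold higher and the histone methyltransferase MLL5 was 2.34-fold higher.

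Among the transcripts that fell, phosphoglycerate dehydrogenase-like (isotig13269), which opens serine synthesis, dropped from 92.8 to 3.71 RPKM and was 25.0-fold lower (12.4 to 58.6). Guanylate cyclase (isotig13105) was 93.0-fold lower (31.5 to 453). Actin related protein 1 (isotig15746) had 301 reads in non-aestivation and 0 in deep aestivation, at least 76.4-fold lower. Bisphosphate nucleotidase fell 24.2-fold (13.3 to 49.1), a fibrinogen C domain-containing protein 23.0-fold (12.7 to 46.7) on isotig16485 and 11.1-fold over 9 isotigs, peptidyl-prolyl cis-trans isomerase 5 26.4-fold (11.0 to 82.5), alpha tubulin 13.5-fold (7.36 to 27.7) and the matrix protein hemicentin-1 11.0-fold (8.25 to 14.9). Complement component 3-2, the central protein of the complement cascade, went from 3075 to 572.4 RPKM and was 5.37-fold lower (4.45 to 6.52).

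Of 43 cell cycle and DNA replication isotigs, 23 fell and 0 rose, with a median log2 ratio of -1.25, below each of 10000 random lists matched on expression. Cell division cycle 2, the kinase that drives entry into mitosis, fell 3.99-fold (2.84 to 5.73), and the replication helicase subunit MCM6 fell 4.71-fold (2.82 to 8.31). In the same libraries, some transcripts known from germ cells, such as the sperm protein bindin, had reads in non-aestivation and few or 0 in deep aestivation. Of 17 tricarboxylic acid cycle isotigs 11 fell and 1 rose (median -1.23, percentile 0.04 among random lists). Malate dehydrogenase (isotig16250) fell 3.38-fold (2.47 to 4.71), the cytosolic form 2.68-fold (2.16 to 3.34) and citrate synthase (isotig15148) 2.62-fold (1.85 to 3.77). Of 32 heat shock protein and chaperone isotigs 15 fell and 0 rose (median -0.99, percentile 0.06). Those that fell included subunits of the cytosolic chaperonin, such as the theta subunit at 4.24-fold on isotig04136 (2.80 to 6.64) and 3.33-fold over its 2 isotigs, and calreticulin-like, a calcium-binding chaperone of the endoplasmic reticulum, at 2.16-fold (1.957 to 2.38), which TMM scaling puts just under 2-fold.

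Translation factors fell in 11 and rose in 0 of 27 isotigs (median -0.87, percentile 0.67), with the helicase eIF4A isoform 1B 3.03-fold lower (2.59 to 3.56). Of 62 ribosomal protein isotigs 2 were higher, 2 lower and 58 within 2-fold, and their median of -0.32 lay at percentile 36.5 among isotigs with a protein match and 0.93 among all isotigs. RNA splicing and processing isotigs fell in 9 and rose in 1 of 28 (median -0.79, percentile 0.89). Antioxidant enzymes fell in 13 and rose in 3 of 46 (median -0.73, percentile 0.54), but their percentile was 14.8 among isotigs with at least 100 reads and 6.09 with 1 isotig per protein name. Thioredoxin domain-containing protein 5, also named endoplasmic reticulum protein ERp46, entered that list by its name and fell 4.06-fold (2.92 to 5.75).

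Electron transport and ATP synthase isotigs fell in 16 and rose in 1 of 49 (median -0.60, percentile 2.505). The nuclear-encoded ATP synthase beta and alpha subunits fell 2.60-fold (2.35 to 2.88) and 2.46-fold (2.22 to 2.72), while the mitochondrially encoded cytochrome c oxidase subunit 1 stood at 10196 and 14975 RPKM, a ratio of 1.47. Extracellular matrix and collagen isotigs fell in 16 and rose in 5 of 43 (median -0.50, percentile 10.8), with the fibrillar collagen alpha 120 and 140 chains 2.72-fold lower, at 2249 and 825.5 RPKM. Ubiquitin and proteasome isotigs fell in 29 and rose in 1 of 71 (median -0.55, percentile 5.59). Complement and lectin isotigs went both ways, 11 higher and 11 lower of 52, and their median of -0.01 (0.10 with TMM) lay at the 98.6th percentile. That position was not kept among isotigs with at least 100 reads (percentile 6.02), with 1 isotig per protein name (92.3) or against random lists of all isotigs (68.9). A C-type lectin domain protein rose 3.51-fold (2.89 to 4.30) and a ficolin 1-like isotig (isotig03772) 4.68-fold (3.74 to 5.92). Both isotigs of hypoxia inducible factor 1 alpha stayed just inside the 2-fold line, at 757.8 and 381.0 RPKM on isotig27066, a log2 ratio of -0.99, and at -0.94 on isotig16875.

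In all, 1430 isotigs were at least 2-fold higher and 2029 at least 2-fold lower in deep aestivation than in non-aestivation, against 310 and 321 on average when the reads of the 2 libraries were redrawn from a common rate. The balance of higher and lower depended on the scaling. Isotigs with a protein match had a median log2 ratio of -0.36 (455 higher, 1374 lower), and those without a match had a median of 0.16 (975 higher, 655 lower). Higher isotigs made up 41.3% of the calls, and 64.9% (2337 higher, 1266 lower) when ratios were centred on isotigs with a protein match, an alternative chosen after seeing the data. The share was 48.7% with TMM factors, which moved the median of all isotigs by 0.11 on the log2 scale, 49.0% with median-of-ratios factors, which moved it by 0.12, and 50.5% among isotigs with at least 100 reads.

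**Figure D1:**
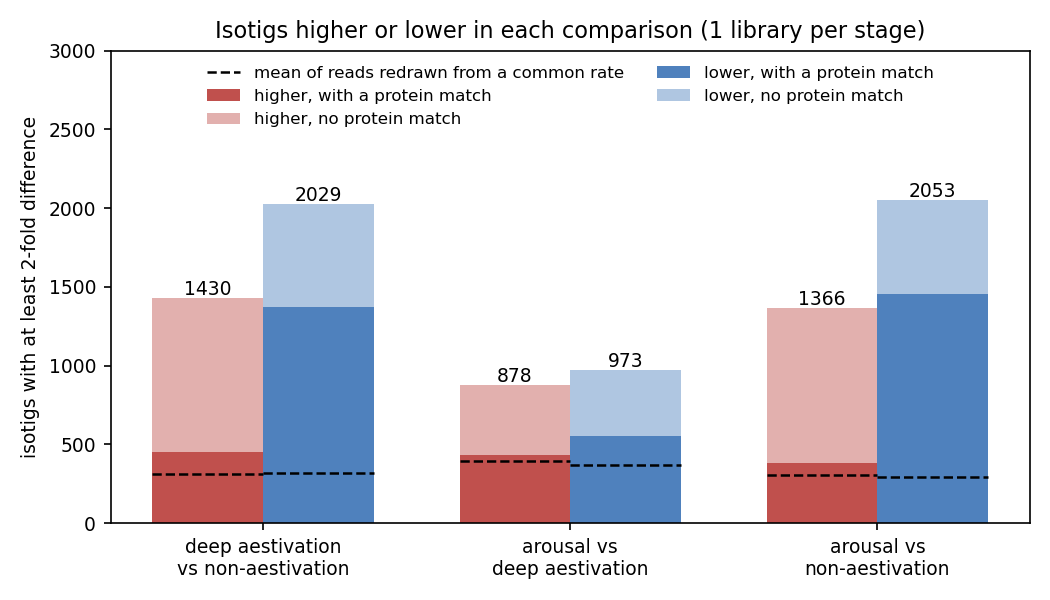
Numbers of isotigs at least 2-fold higher or lower in each comparison on the log2(RPKM + 0.5) scale, split by whether the isotig had a protein match; dashed lines give the mean number when reads were redrawn from a common rate. The bars reach 1430 and 2029 for deep aestivation against non-aestivation but 878 and 973 for arousal against deep aestivation, and most higher isotigs against non-aestivation had no protein match; centring on matched isotigs turned the balance to more higher than lower in every comparison.

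**Figure D2:**
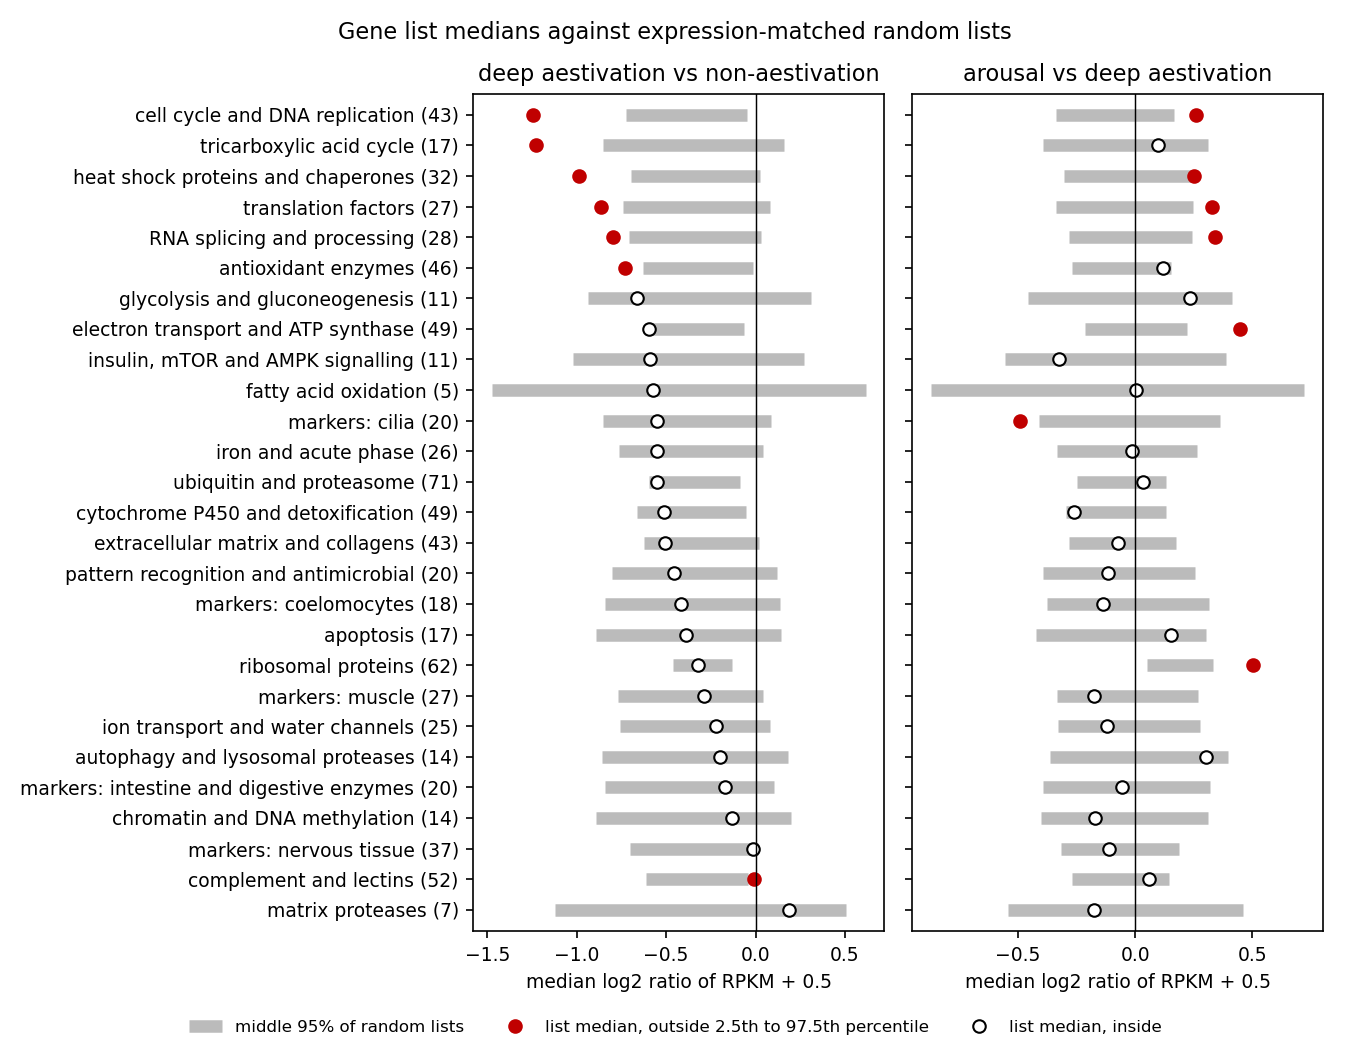
Median log2 ratio of RPKM + 0.5 of each gene list (number of isotigs in brackets), with the middle 95% of 10000 expression-matched random lists as grey bars, for deep aestivation against non-aestivation (left) and arousal against deep aestivation (right). Cell cycle, tricarboxylic acid cycle, chaperone, translation factor, splicing and antioxidant lists lie below their bars on the left, and ribosomal and electron transport lists lie above theirs on the right; the marker list for gonad, whose pattern also matched other proteins, is not drawn.

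The second comparison asked what differs between arousal and deep aestivation. Major yolk protein 1, a Kazal-type protease inhibitor, angiotensin-converting enzyme, ADAMTS7 and FRAS1 were far lower at arousal, and ribosomal proteins, electron transport subunits, translation factors and splicing factors were higher as groups. Major yolk protein 1 went from 22504 to 681.9 RPKM, 33.0-fold lower (31.6 to 34.5). A Kazal-type protease inhibitor (isotig18647) fell 73.5-fold (33.5 to 201), from 406 reads to 6. Angiotensin-converting enzyme had 126 reads in deep aestivation and 1 in arousal, 137-fold lower (24.1 to 5445), and the protease ADAMTS7 had 174 and 1, 189-fold lower (33.5 to 7503). FRAS1, a basement membrane protein, fell 36.2-fold on isotig16081 (12.03 to 178) and 11.7-fold over its 2 isotigs.

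Serum amyloid protein A on isotig08093 returned to 0 reads, at least 47.1-fold lower, while the sum of its 2 isotigs was 7.003-fold lower. Lactase-phlorizin hydrolase on isotig14693 was also at 0 reads, at least 34.5-fold lower, and 2.46-fold lower as the sum of its isotigs. The protein with EGF-like domains that had risen in deep aestivation fell 168-fold (46.2 to 1395), to 4.72 RPKM. A titin isoform fell 10.5-fold on isotig01194 (6.45 to 18.1) and 3.97-fold over its 7 isotigs, and a cytochrome P450 of family 3 fell 2.16-fold (1.71 to 2.75). Apolipoprotein B, the lipid carrier, fell 3.84-fold, from 937.3 to 244.4 RPKM.

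Cathepsin L2, a lysosomal protease, rose 8.45-fold (5.11 to 14.9), a CUB and sushi domain-containing protein 8.01-fold (5.48 to 12.1) and complement receptor type 2-like 7.75-fold (4.25 to 15.5). Complement factor B rose 6.54-fold on isotig00440 (4.08 to 11.0) but 1.75-fold over the sum of its 6 isotigs. Fibrinogen-like protein A rose 5.12-fold on isotig19241 (3.84 to 6.93) and 2.35-fold over the sum of 18 isotigs. Heterogeneous nuclear ribonucleoprotein A/B, an RNA-processing protein, rose 3.30-fold (3.03 to 3.60), from 390.9 to 1291 RPKM. Ribosomal protein P0 (named L10e/P0) had 0 and 161 reads on isotig10296, but its 2 isotigs summed were 1.57-fold higher, and an actin isotig that rose 3.05-fold was 1.12-fold higher in the sum of 4 isotigs. The lists for complement and lectins (8 higher, 6 lower of 52, percentile 87.6), ubiquitin and proteasome (8 higher, 6 lower of 71, percentile 82.7) and autophagy and lysosomal proteases (3 higher, 0 lower of 14, percentile 92.7) lay within the middle 95% of their random lists.

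Ribosomal proteins had a median log2 ratio of 0.50 and electron transport and ATP synthase 0.45, each above all 10000 of its random lists. Most members moved by less than 2-fold, with 4 of 62 ribosomal protein isotigs and 4 of 49 electron transport isotigs higher and 1 lower in each. Ribosomal protein L34 rose 2.31-fold (1.964 to 2.73), and ribosomal protein L13 stood at 3767 and 5171 RPKM. Translation factors (4 higher, 0 lower of 27, median 0.33, percentile 99.4) and splicing factors (3 higher, 2 lower of 28, median 0.34, percentile 99.7) were also high. The cell cycle list (10 higher, 4 lower of 43, median 0.26) lay at the 99.4th percentile and the chaperone list (5 higher, 0 lower of 32, median 0.25) at the 98.1st. Among isotigs with at least 100 reads these percentiles were 75.7 and 72.5, the first over only 6 isotigs. With 1 isotig per protein name they were 88.1 and 97.2, and the chaperone list lay at 95.9 against random lists of all isotigs. The cilia markers had a median of -0.49 (percentile 0.89), or -0.40 with isotigs at 0 reads set to their bound. Of their 20 isotigs 2 were lower, an axonemal dynein heavy chain among them with 18 and 9 reads, a difference not detectable at this depth.

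Arousal had 878 isotigs at least 2-fold higher and 973 lower than deep aestivation, against 394 and 368 with reads redrawn from a common rate. Requiring also that the counting interval exclude equal rates left 530 and 602.

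**Figure D3:**
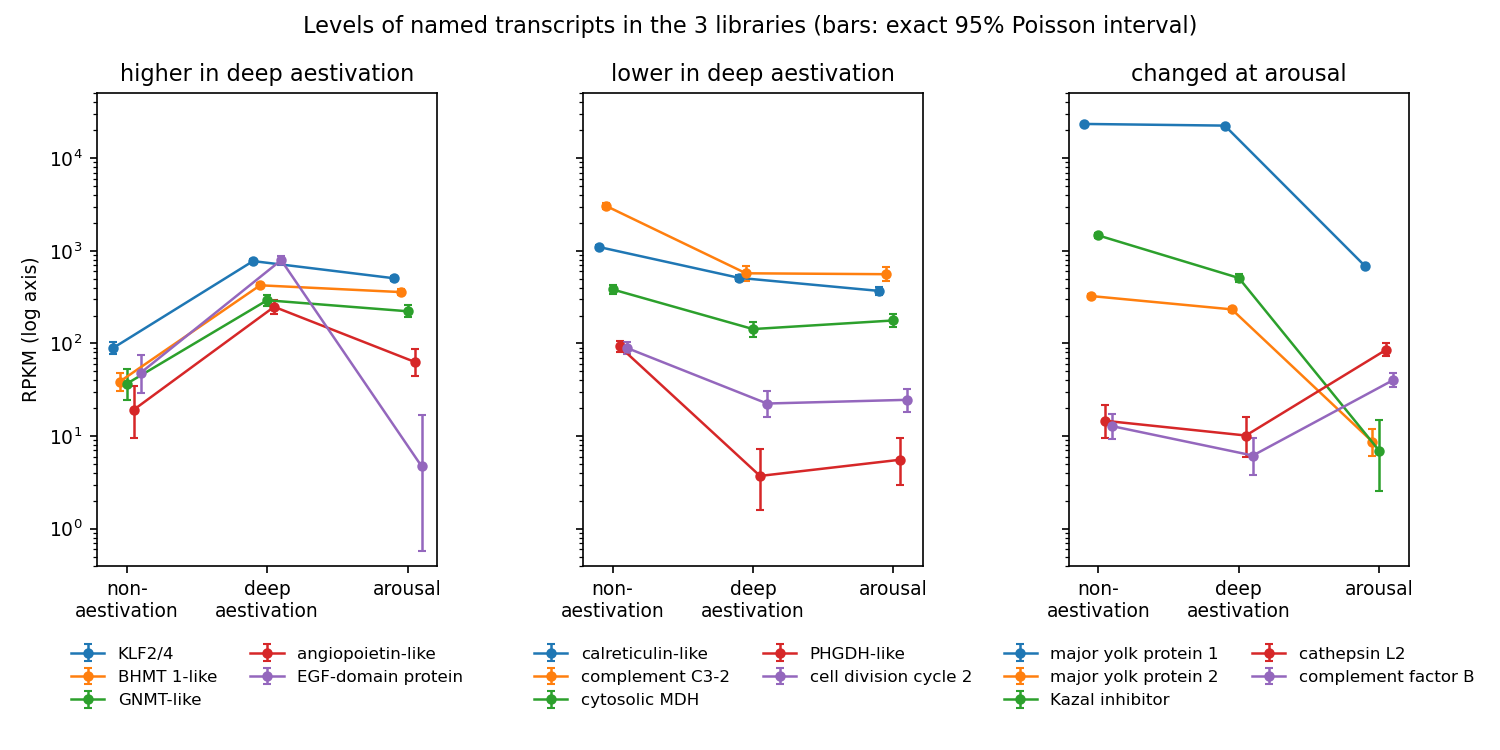
RPKM (log axis) of 15 named transcripts in the 3 libraries, 1 library per stage, with exact 95% Poisson intervals from the read counts. KLF2/4 and BHMT 1-like stay high at arousal, PHGDH-like stays low, and the yolk proteins drop by more than 2-fold only at arousal, from 22504 to 681.9 RPKM for major yolk protein 1.

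The last comparison set arousal against non-aestivation. Betaine-homocysteine S-methyltransferase 1-like was 9.27-fold higher (7.38 to 11.8) and glycine N-methyltransferase-like 6.07-fold higher (4.08 to 9.32). OSBPL10 was 12.5-fold higher (7.93 to 20.8), complement receptor type 2-like 11.0-fold (5.55 to 24.7), lactase-phlorizin hydrolase on isotig08881 8.86-fold (6.14 to 13.2) and histone H1 7.73-fold (4.89 to 12.8). The CUB and sushi domain-containing protein was 6.22-fold higher and cathepsin L2 5.865-fold higher.

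On the other side, the Kazal-type inhibitor was 211-fold lower (96.9 to 577), FRAS1 124-fold lower on isotig16081 (42.1 to 605) and 35.7-fold over its 2 isotigs, and major yolk proteins 1 and 2 were 34.4-fold (32.9 to 36.0) and 37.3-fold lower (26.9 to 53.2). Actin related protein 1 had 301 reads and 1, 308-fold lower (54.8 to 12203), and hemicentin-1 had 124 and 1 on isotig17178 and was 62.1-fold lower over its 2 isotigs. Complement component 3-2 remained 5.49-fold lower (4.57 to 6.64), calreticulin-like 2.99-fold (2.69 to 3.33) and the chaperone gp96 3.01-fold (2.70 to 3.35). Hypoxia inducible factor 1 alpha, the oxygen-sensing transcription factor, was 2.43-fold (1.97 to 3.005) and 2.78-fold lower (2.21 to 3.52) on its 2 isotigs. Cytochrome c fell 2.67-fold (1.99 to 3.62) and aconitase 2, of the tricarboxylic acid cycle, 2.67-fold (2.03 to 3.54).

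Chaperones had a median of -0.95 (15 of 32 lower, percentile 0.16). The tricarboxylic acid cycle list (9 of 17 lower, median -1.01, percentile 0.70) and the cell cycle list (21 of 43 lower, 1 higher, median -0.97, percentile 0.10) lay at 3.58 and 9.22 among isotigs with at least 100 reads. The cell cycle list had only 6 such isotigs. Some transcripts known from germ cells also differed in this comparison, with bindin at 61 and 0 reads. Extracellular matrix isotigs were lower in 16 and higher in 3 of 43 (median -0.70, percentile 2.31), and 15.3 with 1 isotig per name, 3.29 among isotigs with at least 100 reads and 2.65 with a pseudocount of 0.1. Ubiquitin and proteasome isotigs were lower in 29 and higher in 1 of 71 (median -0.65), at percentile 2.56, at 2.27 with TMM and at 18.02 among isotigs with at least 100 reads. Ribosomal proteins had a median of 0.22 (percentile 99.7), which was 70.9 among isotigs with at least 100 reads and 69.9 against random lists of all isotigs. In total 1366 isotigs were higher and 2053 lower, against 309.0 and 291 with reads redrawn from a common rate. Higher isotigs made up 40.0% of these calls, 48.2% with TMM factors, 48.5% with median-of-ratios factors, 51.2% among isotigs with at least 100 reads, and 68.2% (2453 higher, 1142 lower) with ratios centred on isotigs with a protein match.

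Return at arousal was measured on the isotigs that had changed in deep aestivation. Of the 1430 that had risen, 256 (17.9%) turned back by at least 2-fold, and 875 (61.2%) were still at least 2-fold above non-aestivation. Of the 2029 that had fallen, 549 (27.1%) turned back and 1112 (54.8%) were still at least 2-fold below. Since the deep aestivation library enters both steps, part of such turning back comes from its counting error, and reads simulated with arousal equal to deep aestivation gave 3.56% and 13.0% turned back, and 80.1% and 70.8% still changed. Splitting the deep aestivation reads between the 2 steps lowers the depth of that library in each, and 1485 isotigs had then risen and 2336 fallen. Of these, 18.0% and 23.2% turned back, and 57.4% and 48.6% were still changed. The 875 and 1112 isotigs shared by the 2 comparisons against non-aestivation stand beside 133 and 47.1 with no effect simulated and 179 and 382 for independent lists. Part of the excess may come from the shared library. The log2 ratios of those comparisons had a correlation of 0.71 across isotigs (0.49 simulated) and a covariance of 0.98 (0.12 simulated).

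Markers of other tissues, fixed as lists, gave the following medians against non-aestivation, in deep aestivation and then arousal. Muscle genes had -0.29 and -0.62, and in deep aestivation 5 of 27 isotigs were lower, 2 higher and 20 within 2-fold. The myosin heavy chain on isotig06040 was 2.62-fold lower in deep aestivation (2.34 to 2.93). Titin-like (isotig13411), the most abundant of them, had a ratio of 1.53 (1.40 to 1.68). Intestinal and digestive enzymes had -0.17 and -0.14, and a trypsin-like serine protease went from 978.0 to 1396 and 2277 RPKM. Coelomocyte genes had -0.42 and -0.61, with the actin-severing protein gelsolin 2.52-fold lower in deep aestivation (2.14 to 2.98). Nervous tissue genes had -0.01 and -0.10, and ciliary genes had -0.55 and -0.72. The gonad list, whose pattern also matched many proteins with binding in their names, had -0.37 and -0.49. With bindin taken as a whole word, an alternative added later, 21 isotigs had -0.71 (percentile 8.84) and -0.92 (percentile 2.87). All these marker lists lay within the middle 95% of their random lists in these comparisons. Exceptions under alternatives were the digestive enzymes among isotigs with at least 100 reads (percentiles 98.1 and 99.9, medians 0.37 and 0.71), and nervous tissue genes at arousal with 1 isotig per name (99.8). Against random lists of all isotigs, muscle genes at arousal (1.30) and gonad genes in both stages (1.24 and 0.04, or 2.35 and 0.46 with the corrected pattern) also lay outside. The medians of nervous tissue genes turned positive with TMM, at 0.10 and 0.01.

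The remaining lists lay within the middle 95% of random lists drawn from isotigs with a protein match in every comparison, and are given as medians in deep aestivation against non-aestivation. They were -0.66 for glycolysis, -0.59 for insulin, mTOR and AMPK signalling, -0.57 for fatty acid oxidation, -0.55 for iron and acute phase proteins, -0.51 for cytochrome P450 and detoxification, and -0.45 for pattern recognition. They were -0.39 for apoptosis, -0.22 for ion transport, -0.20 for autophagy and lysosomal proteases, -0.13 for chromatin and DNA methylation, and 0.19 for matrix proteases. Against random lists of all isotigs, iron and acute phase proteins (percentile 2.30) and cytochrome P450 (1.36, and 1.62 and 0.81 for arousal against deep aestivation and non-aestivation) lay outside in deep aestivation, as did electron transport (0.05), ubiquitin and proteasome (0.16) and extracellular matrix (0.94). Lists of fewer than 5 measured isotigs got no percentile: the median was -0.59 for hypoxia and oxygen, -0.96 for lipid synthesis and -1.11 for histones. Iron and acute phase isotigs went both ways, 4 higher and 11 lower of 26, and at arousal against non-aestivation their percentile was 66.2 but 0.03 with 1 isotig per name. The scavenger receptor cysteine-rich protein on isotig14875, a pattern recognition protein, was 3.23-fold lower in deep aestivation (2.54 to 4.13), and cathepsin D, a lysosomal protease, was 2.53-fold lower on isotig06265 (1.98 to 3.25). The proteasome subunit alpha type 4 was 3.71-fold lower (2.71 to 5.17), protein arginine methyltransferase 1-like 4.97-fold lower (3.25 to 7.87) and aldehyde dehydrogenase 9 2.66-fold lower (1.97 to 3.62).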

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

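Centring on isotigs with a protein match, random lists from all isotigs, the corrected gonad pattern and sums over 1 name were chosen after seeing the data. Numbers of calls moved mainly with the read filter, which changes how many isotigs are tested. Without a filter 3527 isotigs were higher and 5701 lower in deep aestivation than in non-aestivation, 3356 and 3558 in arousal than in deep aestivation, and 3463 and 5724 in arousal than in non-aestivation. With at least 100 reads these were 540 and 529, 171 and 177, and 516 and 491. Centring gave 2337 and 1266 for deep aestivation and 2453 and 1142 for arousal, both against non-aestivation; the majority then changed sides, as it did narrowly with at least 100 reads. The interval criterion left 530 and 602 calls in arousal against deep aestivation. All counts stayed within 1.5 times under both pseudocounts, TMM, median-of-ratios and totals without the most abundant isotigs. Against random lists of all isotigs, 13 lists instead of 6 lay below the middle 95% in deep aestivation, 10 instead of 4 in arousal (both against non-aestivation), and 2 instead of 1 in arousal against deep aestivation. With 1 isotig per name, 2 lists instead of 1 lay below it in arousal against deep aestivation, and 2 instead of 1 lay above the middle 95% in arousal against non-aestivation; the cause was not tested. The share of fallen isotigs that turned back was 30.1% with TMM and 23.2% with split reads, against 27.1%. Pearson's r was 0.77, 0.88 and 0.78 with a pseudocount of 1, in the order of the comparisons, and 0.88 and 0.76 with at least 100 reads for the comparisons with arousal. No ratio of a named isotig past 2-fold changed sign under TMM, a pseudocount of 0.1 or sums over 1 name, but some ratios near 1 did, such as major yolk protein 1 in deep aestivation under TMM. TMM brought 8 called ratios just under 2-fold, calreticulin-like, caspase-3 and hnRNP A/B in deep aestivation among them, and summing isotigs of 1 name took 10 under 2-fold, some far under, such as actin at arousal. No paired analysis was possible because each stage had 1 library, and for the same reason no library could be left out. Depth limits rare transcripts: even among the 10896 isotigs that passed the filter of at least 20 summed reads, the median was 20 to 23 reads per library.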

Other observations

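The tests of isotig length, read depth, scaling, yolk protein copies and the cell cycle list below were chosen after their results were seen, while the germline and meiosis list and both its tests were fixed before its counts were looked at. Methionine and serine metabolism was followed further because its enzymes were among the largest changes in deep aestivation, and these isotigs were chosen after their values were seen. Besides the enzymes described above, methionine adenosyltransferase, which makes S-adenosylmethionine, was 2.46-fold higher in deep aestivation than in non-aestivation (2.15 to 2.83) and 1.37-fold at arousal. Sarcosine dehydrogenase, which acts on the product of glycine N-methyltransferase, was 3.32-fold higher (1.83 to 6.40), and dimethylglycine dehydrogenase had a ratio of 1.85 (1.36 to 2.54). A shorter isotig of betaine-homocysteine methyltransferase had 22, 30 and 23 reads. An isotig of 5-methyltetrahydrofolate-homocysteine methyltransferase, of the folate-dependent route to methionine, went the other way. It was 3.63-fold lower (2.46 to 5.49) in deep aestivation and 8.12-fold lower (4.81 to 14.6) at arousal. Other enzymes of that route were not examined. Homocysteine S-methyltransferase-like was 2.40-fold lower in deep aestivation (1.94 to 3.0). Guanidinoacetate N-methyltransferase, which uses methyl groups for creatine, had 30, 1 and 2 reads. All 3 enzymes of serine synthesis from glycolysis were lower in deep aestivation: phosphoglycerate dehydrogenase as given above, phosphoserine aminotransferase 2.37-fold (1.63 to 3.49) and phosphoserine phosphatase 4.49-fold (2.78 to 7.57).

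Fatty acid synthase-like had 50 reads in non-aestivation and 1 in each of the other libraries, 47.1-fold lower in deep aestivation (8.08 to 1898). Fructose-1,6-bisphosphatase on isotig16469, an enzyme of glucose synthesis, was 8.31-fold lower (4.44 to 17.2). The 2 late histone H1 isotigs had 16, 4 and 17 and 17, 6 and 13 reads in the 3 stages, while the histone H1 of isotig22036 had 21, 77 and 166. A complement factor H-like isotig (isotig27723) had 67 reads in non-aestivation and 0 in the other libraries, and another (isotig23867) had 71, 25 and 33.

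Some transcripts known from germ cells, chosen after their values were seen, were concentrated in the non-aestivation library. Bindin, the sperm protein that binds the egg, had 61 reads there and 0 in the other libraries. Flagellar creatine kinase had 34, 2 and 0 reads, and SYCP1, a synaptonemal complex protein, 23, 0 and 1. Mitochondrial creatine kinase, whose name does not tie it to germ cells, had 54, 0 and 0. Guanylate cyclase, grouped with them, had 296, 3 and 57 reads and so was 17.5-fold higher at arousal than in deep aestivation (5.69 to 87.4), unlike the others. Most of the 21 isotigs of the corrected gonad list did not differ by 2-fold from non-aestivation. In deep aestivation 8 were lower, 0 higher and 13 within 2-fold (percentile 8.84). At arousal 9 were lower, 0 higher and 12 within 2-fold (percentile 2.87). The 9 isotigs of the germline and meiosis list had 23, 5 and 4 reads, with 3 of the 9 seen in each later stage. They included a sperm cation channel subunit and a receptor for egg jelly. They also included hyperpolarization-gated channels, whose names do not tie them to germ cells. Of these channels, isotig14395 had 4, 0 and 1 reads, isotig24298 3, 1 and 1, and isotig26270 1, 0 and 0. The larger of the germline list's ratios to non-aestivation was 0.231 (0.0685 to 0.620). Gonad RNA in that library is a candidate explanation that these few reads leave open, as is expression in the respiratory tree itself. Whether it may account for all the cell cycle differences stays open too. The cell cycle list was higher in arousal than in deep aestivation, at percentile 99.38, but at 75.7 among its 6 isotigs with at least 100 reads. Both libraries had 0 reads of bindin, but a sperm protein cannot show whether other gonad RNA was present.

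Isotigs with a protein match were lower and those without were higher in both later stages, with gaps between their medians of 0.52 in deep aestivation and 0.60 in arousal on the log2 scale. Isotigs without a match took 39.8%, 47.6% and 52.0% of the reads in the 3 stages, and 29.9%, 34.9% and 36.2% without the 3 most abundant of them. Isotig length does not account for all of it, since the smallest gap within length quartiles was 0.32 (bootstrap interval over isotigs 0.21 to 0.40). Nor does read depth, with a smallest gap of 0.43 (bootstrap interval 0.35 to 0.60) within quartiles of reads. The gap in deep aestivation was 0.62 in quartile 1 and 0.32 in quartile 4 of length, so a part played by length stays open. Differences in RNA integrity, in library preparation and in the stages themselves were not tested and cannot be separated with 1 library per stage.

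Major yolk protein 1 was nearly level from non-aestivation to deep aestivation, a ratio of 0.959 (0.949 to 0.970), and fell at arousal. A few abundant isotigs setting the scale do not account for the fall, which was -5.10 on the log2 scale when scaled to the remaining reads. Reads divided among the 4 isotigs named major yolk protein do not either, since together they fell by 5.04. Of their 61570 reads in deep aestivation, 60653 were on the isotig of major yolk protein 1. Reads dropped for matching several isotigs are not in the counts, so their part was not tested. Gonad RNA lost at arousal may still contribute: the germline list had a ratio of 0.737 between arousal and deep aestivation, with an interval from 0.146 to 3.42 that decides nothing. Bindin was already at 0 reads in deep aestivation, where major yolk protein 1 was at 22504 RPKM. As a sperm protein, bindin cannot show whether other gonad RNA was present, so this decides nothing either. A change in the tissue itself was not tested against differences among the animals used.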
